A study of Arabidopsis thaliana with 6 samples.

How the data were processed

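Total RNA from guard cell protoplasts was labelled with a single dye and hybridised to 6 Agilent arrays, 3 of wild type and 3 of aks1aks2-1, per the labels. Groups and replicate numbers came from the sample titles. The series text calls the experiments independent but does not say how plants or days were shared between genotypes, so p-values measure the spread between these samples.

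Per the file headers, the deposited scanner files hold intensity values from Agilent Feature Extraction, version 10.7.1.1 for the arrays of slide 1 and version 9.5.1.1 for those of slide 2. The processed intensity is background-subtracted and detrended within the array, and dim values are replaced by a surrogate, per the file headers. No normalization between arrays is recorded there. The files also hold flags for signal well above background, saturation and outlier spots. A deposited value table of the authors holds intensity on a linear scale. Each of its 6 columns had a median of 186, followed the ranks of its own array's processed signal with a Spearman coefficient of 1.00 across probes, and matched the sorted values of the first column within 0.0953%. It is therefore quantile-normalized and not centred per gene, and the software used for it is not given in the sources used here.

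From the scanner files, 1417 control spots and outlier-flagged spots were left out, spots of a probe were averaged, and log2 processed signal minus the 75th percentile of the array was taken. Of 43603 probes 39275 carried a locus and 452 carried several. The locus was found in the reference gene table (assembly TAIR10.1, used for names and gene order) for 38848 probes, and the array's own name was kept otherwise. Probes were kept if well above background on all 3 arrays of at least 1 genotype, and a gene was read from its brightest probe. This left 20480 genes. Among 25 named genes with several probes well above background on all 6 arrays, the probes of 3 differed in sign and those of 1, SUC2, by over 0.5. All 11 targeted and channel genes have 1 probe.

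Genotype was tested with lmFit and eBayes in limma 3.58.1 under R 4.3.3, with the packages data.table (version 1.17.8) and statmod (version 1.5.0), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, beside an estimated correlation and fry. In the directional test of fry, which asks whether genes of a set move on balance one way, 0 lists passed, with a smallest adjusted p of 0.910. With replicate number as a block it was 0.213, again with 0 lists. The mixed test of fry, for change in either direction, passed 0 lists without the block and 5 with it, which were guard cell identity, jasmonate, salicylate, clock and vascular genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Named genes followed a rule set before the data were examined, which takes all targeted and inward channel genes, the 4 members with the smallest p of each other list, and 12 genes in each direction. As no gene passed, these 12 were genes with a mean difference of at least 1 and 3 differences over 0.5 of one sign, ordered by the smallest of the 3. There were 61 such genes lower and 24 higher.

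Same-numbered arrays deviated together from their group means, with correlations across genes of 0.912, 0.866 and 0.947 for numbers 1, 2 and 3, so the numbers pair the samples. The pairing comes from the titles, and genes are not independent replicates. Slide and scan batch coincide, and each slide holds both genotypes in equal number. The difference with slide as a block therefore equals the mean of the 3 differences, and replicates 1 and 2 give the value within slide 1 and replicate 3 that within slide 2. Slide 2 holds 1 array of each genotype, which allows no test within it.

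The steps were tested on simulated data made from the spread of the real arrays, for aks1aks2-1 against wild type over 20480 genes, with 100 genes changed by log2 1 and 100 by log2 2. Without a block, 0 and 0 were recovered. With slide as a block 0 and 51 were recovered. With replicate number as a block 99 and 100 were recovered, with 25 false among 224 calls, and as a random block 99 and 100, with 27 false among 226. The simulated noise was normal, its variances were already drawn towards a common value, and arrays of a pair shared their mean exactly. On the real arrays the fit with replicate number as a block called 0 genes. The share recovered in the simulation therefore need not hold for them. Of 20 lists shifted by 0.3, 20 were recovered with 0 false calls, for lists whose genes vary independently.

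The alternatives set before the data were examined were normexp background correction with an offset of 50, quantile and median normalization, other filters on dim probes, slide and replicate number as blocks, slide 1 alone, trend and robust variance, the mean of probes, the authors' value table, outlier spots kept, a 2-fold minimum and leaving out each array. The sign of each list median was also checked under the scalings. A further 15 fits with the replicate number were added after the data were seen.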

Results

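Transcript levels were measured in guard cell protoplasts, which are wall-less cells prepared from the pores of the leaf epidermis, of *Arabidopsis thaliana*. Wild-type plants were compared with the mutant aks1aks2-1, labelled as lacking normal function of AKS1 and AKS2, basic helix-loop-helix transcription factors. Each genotype had 3 arrays, and the series text states that the experiments were independent. Of 43603 probes, 30394 and 31271 were well above background in wild type and aks1aks2-1 replicate 1, 29859 and 32711 in replicate 2, and 41305 and 41888 in replicate 3. No probe was saturated. Replicates 1 and 2 lay on slide 1, and replicate 3 lay on slide 2, which was scanned and extracted with other software. The number of arrays limits the precision of all values below, which are log2 signals relative to the 75th percentile of the array, and differences are aks1aks2-1 minus wild type.

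The first question was whether transcripts of the targeted genes differed. AKS1 (AT1G51140) averaged -0.87 ± 1.54 (SD, n = 3) in wild type and -2.01 ± 0.96 in aks1aks2-1. AKS1 was lower by a log2 difference of -1.14, with differences of -0.55 and -1.16 for replicates 1 and 2 on slide 1 and -1.71 for replicate 3 on slide 2. AKS2 (AT1G35460) averaged 0.95 ± 0.23 and 0.69 ± 0.35, a difference of -0.26, with -0.01, -0.18 and -0.60 in replicates 1, 2 and 3. Their relatives AKS3 (AT2G42280) and FBH2 (AT4G09180) differed by 0.02 and 0.06. In limma, 0 of these 4 genes passed over all genes or adjusted over the list alone, with an adjusted p of 1.00 for AKS1 and a 95% interval of -3.22 to 0.94. With replicate number as a block the interval of AKS1, not adjusted for the number of genes, was -1.74 to -0.54, and 1 gene, AKS1, passed adjusted over the list alone, while its adjusted p over all genes was 0.225. Leaving out wild type replicate 3 gave -0.37 for AKS1, and leaving out wild type replicate 1 gave -1.92. Each leaves an aks1aks2-1 array unpaired, so the differences of AKS1 between experiments enter these values. The pairs of slide 1 alone had a mean difference of -0.86. Leaving out wild type replicate 1 also brought the list of 4 genes from an adjusted p of 0.0764 in camera to 0.0248. With an estimated correlation and all arrays the adjusted p of that list was 0.371. The AKS1 probe lies at chromosome 1, 18943954 to 18944097, and the AKS2 probe at chromosome 1, 13041715 to 13041883, on build ath1:Jan2004, with the exon or UTR not known. The insertion positions are not given in the sources used here, so either probe may lie outside the affected part and would then check nothing.

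The topic of the series is potassium uptake, so the Shaker channels that carry or regulate inward potassium currents were compared next. KAT2 (AT4G18290), a main guard cell channel, averaged 2.2 ± 0.20 (SD, n = 3) in wild type and 2.25 ± 0.15 in aks1aks2-1, a difference of 0.05. KAT1 (AT5G46240), another guard cell inward channel, differed by -0.05, with 0.02, -0.24 and 0.07 in replicates 1, 2 and 3. AKT1 (AT2G26650) differed by -0.39, with -0.37, -0.72 and -0.09. AKT5 (AT4G32500) differed by -0.28, with -0.38, -0.34 and -0.11. The silent subunit KC1 (AT4G32650) and AKT2 (AT4G22200) had no common direction, with -0.88, -0.10 and 0.22 for KC1 and 0.59, -0.29 and -0.50 for AKT2. AKT6 (AT2G25600) was well above background on 1 wild-type and 2 aks1aks2-1 arrays and was not tested. In limma, 0 of the 6 tested channels passed, over all genes or adjusted over the list alone. The 95% interval ran from -1.81 to 1.71 for KAT1 and from -0.50 to 0.60 for KAT2, and with replicate number as a block from -0.29 to 0.19 and from -0.13 to 0.23. With the block the intervals of AKT1, -0.75 to -0.03, and AKT5, -0.50 to -0.05, lay below 0 before adjustment, with adjusted p over all genes of 0.381 and 0.344, and 0 channels passed adjusted over the list alone. As a set the 6 channels had a median difference of -0.16, with -0.17, -0.26 and -0.04 in the 3 experiments, and an adjusted p of 0.0769 in camera. The list was taken from the topic of the series and is not independent of it. With normexp background correction AKT5 differed by -0.087.

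**Figure D1:**
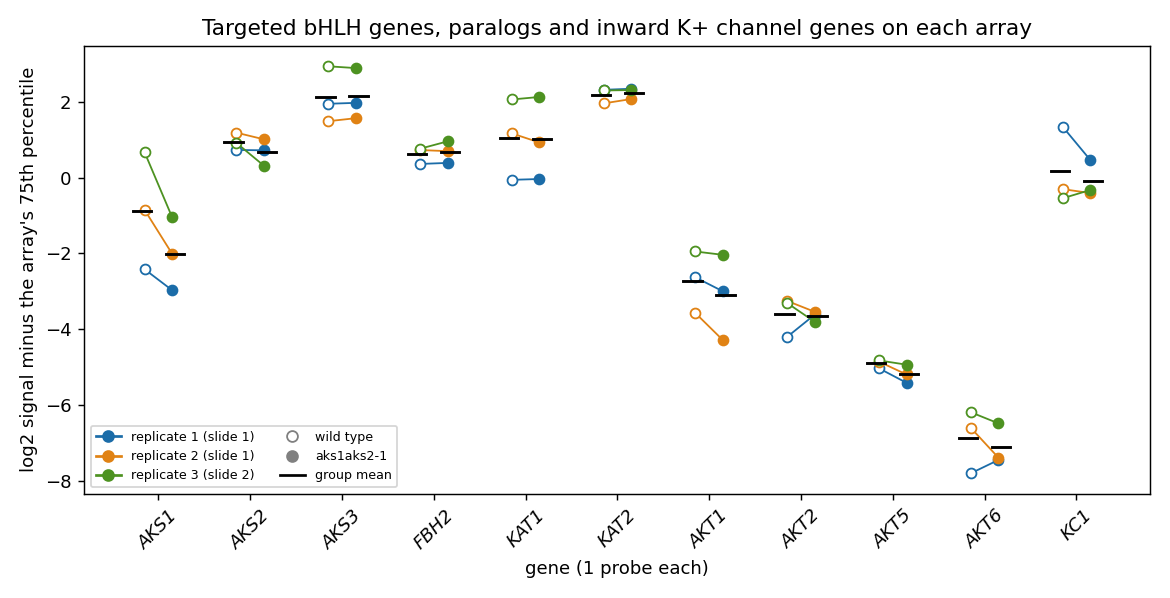
Signal of the targeted genes, their relatives and the inward potassium channel genes on each array, in log2 relative to the array's 75th percentile, with open points for wild type, filled points for aks1aks2-1, lines joining arrays of one replicate number, and bars for group means. AKS1 was lower in aks1aks2-1 in each replicate, by differences of -0.55, -1.16 and -1.71, while KAT1 and KAT2 differed by -0.05 and 0.05 on average.

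Across the genome the largest repeated differences were decreases in signal. AT5G24240, annotated as a phosphatidylinositol 3- and 4-kinase family and ubiquitin family protein, averaged 0.20 ± 1.32 (SD, n = 3) in wild type and -4.88 ± 0.36 in aks1aks2-1, a difference of -5.08, with -6.32, -5.69 and -3.24 in replicates 1, 2 and 3. AT5G48430, annotated as an aspartic endopeptidase, differed by -2.44, the transcription factor bZIP3 (AT5G15830) by -2.41, and AT5G02890, annotated as a transferase, by -2.02. The leucine-rich repeat kinase gene AT1G05700 differed by -1.99 and the O-methyltransferase gene AT1G77530 by -1.36. AT1G53635 differed by -2.36, AT1G72416 by -1.92, AT2G15780 by -1.81, AT5G44380 by -1.67, the monodehydroascorbate reductase gene MDHAR (AT3G09940) by -1.60 and AT1G27020 by -1.52. AT2G15780 and MDHAR were well above background on 2 of 3 aks1aks2-1 arrays. Among genes with higher signal, QQS (AT3G30720), an orphan gene linked to starch metabolism, averaged -0.25 ± 0.50 and 1.27 ± 0.14, a difference of 1.52, with 1.3, 1.33 and 1.93. The lipase gene DGL (AT1G05800) differed by 1.77, the arabinogalactan protein gene AGP4 (AT5G10430) by 1.25, bHLH38 (AT3G56970), a regulator in iron deficiency, by 1.23, AT2G30766 by 1.18, the defensin-like gene AT3G05730 by 1.18, AT2G14247 by 1.11 and AT5G35375 by 1.05. LBD31 (AT4G00210) differed by 2.01, AT2G29770 by 1.95, AT1G55430 by 1.24 and GH9B15 (AT4G23560) by 1.2, and each of these 4 was well above background on 1 of 3 wild-type arrays, and bHLH38 on 2 of 3.

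In limma, 0 of 20480 genes passed an adjusted p of 0.05, with 82 at an unadjusted p under 0.05. With slide as a block 0 passed and 452 had an unadjusted p under 0.05, and with replicate number as a block 0 passed and 2480 did, with a smallest adjusted p of 0.134. These 24 genes are therefore given as values, ranked by the smallest of their 3 differences. With replicate number as a random block, a fit added after the data were seen, 149 genes passed, 32 higher and 117 lower, among them AT5G24240 (adjusted p = 0.0272), QQS (0.0176) and AT1G05700 (0.0129). That was 1 of 15 fits with the replicate number that were added in this way, and their counts ran from 0 to 984. In the simulation the random block fit made 27 false calls among 226, a larger share than the threshold of 0.05 allows. Its adjusted p, here and below, may therefore be too small. With normexp background correction the differences were -4.02 for AT5G24240, -0.96 for AT1G05700, -1.22 for AT5G02890, 0.37 for bHLH38, 0.05 for GH9B15, 0.30 for AT2G29770, 0.44 for LBD31 and 0.19 for AT1G55430. Of the 24 genes, 12 moved by over 1.5 times without some array and 0 changed sign. Each such fit leaves the partner of the array unpaired, so differences between experiments enter the value. The same-numbered differences were -1.65, -2.19 and -1.58 for AT2G15780 and -1.83, -1.38 and -1.35 for AT1G27020. They were 1.29, 0.87 and 1.39 for AT3G05730. Without wild type replicate 3 the difference was -0.33 for AT2G15780, -0.31 for AT1G27020, -1.41 for AT1G53635 and -1.01 for MDHAR, and 3.02 for LBD31. Without aks1aks2-1 replicate 3 it was 0.13 for AT3G05730, 0.52 for AGP4 and 0.62 for GH9B15. Without aks1aks2-1 replicate 2 it was -0.93 for AT5G44380 and 0.71 for AT2G30766, without aks1aks2-1 replicate 1 1.02 for DGL, and without wild type replicate 2 0.79 for AT1G55430.

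**Figure D2:**
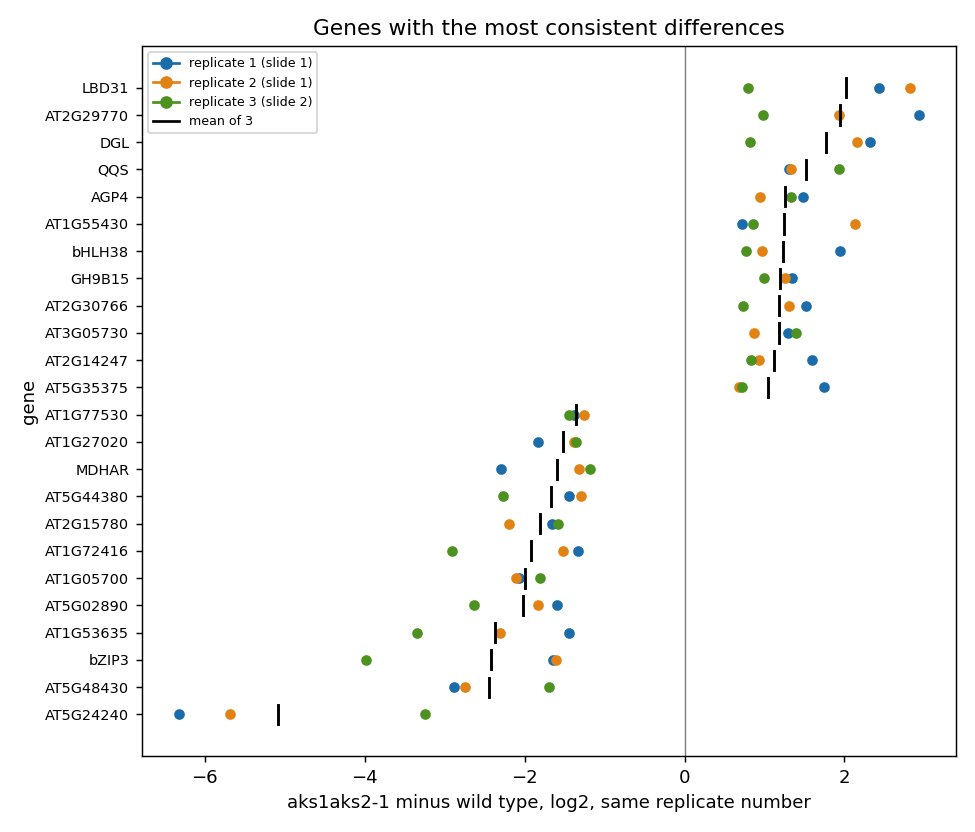
Difference between aks1aks2-1 and wild type, in log2, for the 12 lower and 12 higher genes, with 1 point for each replicate number and a bar for the mean. The genes were selected for differences of one sign in the 3 replicates, and the means run from -5.08 for AT5G24240 to 2.01 for LBD31, which was well above background on 1 of 3 wild-type arrays and differed by 0.44 with normexp background correction.

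Of 15 gene lists tested with camera at a preset correlation, 5 passed, 1 upward and 4 downward. With an estimated correlation 0 passed, with a smallest adjusted p of 0.104. The correlation was estimated at 0.508 for heat shock and 0.318 for jasmonate genes. It was -0.045, -0.016 and -0.038 for vascular, transport and salicylate genes, under the preset 0.01. The loss of these 3 calls therefore cannot be put down to correlation between their members. With an estimated correlation the test rests on the few residual degrees of freedom of these arrays, which raises its p-values. The loss of these calls therefore decides little. Heat shock genes were the list called upward at the preset correlation. Of the 20 measured heat shock members 19 were higher in all 3 experiments, and the median difference was 0.29 (0.37, 0.18 and 0.25 in replicates 1, 2 and 3). The chaperone genes HSP17.6B (AT2G29500), HSP21 (AT4G27670), HSP18.2 (AT5G59720) and HSP15.7 (AT5G37670) differed by 0.47, 0.40, 0.37 and 0.29. The set had an adjusted p of 8.55e-06 in camera, and an adjusted p of 0.371 with an estimated correlation. In limma 0 members passed over all genes or adjusted over the list alone, and 10 were higher adjusted over the list alone with replicate number as a block. Leaving out wild type replicate 2 gave an adjusted p of 0.309 and leaving out aks1aks2-1 replicate 3 gave 0.622. Over the 64 named list genes that could be fitted without each array in turn, which leaves its partner unpaired, 60 moved by over 1.5 times without some array and 33 changed sign. Differences between experiments enter these values, so a sign can change where the pairs agree. CDF2 (AT5G39660) changed sign in this way although its 3 same-numbered differences were -0.35, -0.41 and -0.28.

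Vascular markers were called lower as a set at the preset correlation, with a median difference of -0.43 over 11 members. It was -0.16, -0.63 and -0.45 in replicates 1, 2 and 3, and -0.53 on slide 1. SWEET11 (AT3G48740) and SUC2 (AT1G22710), which export and load sucrose in the phloem, differed by -1.08 and -0.68. The phloem lectin gene PP2-A1 (AT4G19840) differed by -0.60 and the proton pump gene AHA3 (AT5G57350) by -0.59. The set had an adjusted p of 8.55e-06 in camera, and an adjusted p of 0.104 with an estimated correlation. The correlation estimated for this set was -0.045, under the preset. In limma 0 members passed over all genes or adjusted over the list alone, and 5 were lower adjusted over the list alone with replicate number as a block. With replicate number as a random block, added after the data were seen, AHA3, PP2-A1 and SWEET11 passed over all genes, with adjusted p of 0.0316, 0.0322 and 0.0486. Leaving out wild type replicate 2 gave an adjusted p of 0.0866 and leaving out aks1aks2-1 replicate 3 gave 0.0551. Without wild type replicate 3 SWEET11 differed by -0.43 and SUC2 by -0.22, while AHA3 and PP2-A1 moved by less than 1.5 times without any 1 array. The 3 SUC2 probes differed among themselves by up to 0.61, with -0.27 and -0.07 for the probes other than the brightest, which was the one used.

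Jasmonate genes were called lower as a set at the preset correlation, with 21 of 23 measured members lower on average. Their median difference was -0.18 (-0.19, -0.20 and -0.12). The repressor genes JAZ5 (AT1G17380), JAZ2 (AT1G74950) and JAZ1 (AT1G19180) differed by -0.37, -0.22 and -0.18, while VSP2 (AT5G24770), a jasmonate-induced storage protein gene, had no common direction, with 0.36, -0.70 and -1.42. The adjusted p was 0.000395 in camera, and an adjusted p of 0.371 with an estimated correlation. Without aks1aks2-1 replicate 1, aks1aks2-1 replicate 2 or wild type replicate 3 it was 0.0882, 0.475 and 0.867. Salicylate and defence genes had a median difference of -0.11 (-0.10, -0.10 and -0.07), with 16 of 21 lower on average. Their call as a set was lost with an estimated correlation and without any 1 array. ICS1 (AT1G74710), the salicylate synthesis gene, differed by -0.39 and WRKY18 (AT4G31800) by -0.17. The kinase gene FRK1 (AT2G19190), well above background on 2 of 3 aks1aks2-1 arrays, had no common direction, with -1.53, -1.79 and 0.26, and neither had PR5 (AT1G75040), with 0.61, -0.08 and 1.36. The adjusted p was 0.0301 in camera, and an adjusted p of 0.239 with an estimated correlation. Without replicates 1, 2 and 3 of wild type it was 0.513, 0.0959 and 0.195, and without those of aks1aks2-1 0.0955, 0.30 and 0.130. The remaining guard cell transport genes had a median difference of -0.05 (-0.05, -0.10 and -0.04), with 22 of 32 lower on average. Their call as a set was lost with an estimated correlation. The anion exchanger gene CLCA (AT5G40890) differed by -0.43, the outward potassium channel gene SKOR (AT3G02850) by -0.38, the proton pump gene AHA2 (AT4G30190) by -0.34 and CNGC5 (AT5G57940) by -0.26. The adjusted p was 0.0137 in camera, and an adjusted p of 0.219 with an estimated correlation. Without replicates 1, 2 and 3 of wild type it was 0.108, 0.473 and 0.0792, and without those of aks1aks2-1 0.100, 0.00724 and 0.504, while normexp background correction gave 0.0969 for this list and for the salicylate list. In these 3 lists, 0 members passed in limma over all genes or adjusted over the list alone.

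The other lists did not pass. Abscisic acid perception and signalling genes had a median difference of -0.02 over 39 members, or 0.00 with median scaling (adjusted p = 0.067 in camera). The adjusted p was 0.0429 with slide as a block, 0.0372 with the mean of probes and 0.0403 without aks1aks2-1 replicate 3. With an estimated correlation it was an adjusted p of 0.516. The receptor gene PYL6 (AT2G40330) differed by -1.81, with -0.97, -1.90 and -2.57, and by -1.17 without wild type replicate 3, and the receptor genes PYR1 (AT4G17870) and PYL4 (AT2G38310) by -0.33 and -0.28, and NCED3 (AT3G14440), a synthesis gene, by -0.25. Among the abscisic acid and drought responsive genes the median was -0.04 over 23 members (adjusted p = 0.275, 0.0403 without aks1aks2-1 replicate 3, and an adjusted p of 0.751 with an estimated correlation), with EM6 (AT2G40170) at -0.50 and RD29A (AT5G52310) at 0.24. Clock and flowering genes had a median of -0.05 over 26 members, with an adjusted p of 0.106, and an adjusted p of 0.00742 with replicate number as a block. The block gave 1 higher and 2 lower clock members adjusted over the list alone, and the adjusted p with both the block and an estimated correlation was 0.386. Without wild type replicate 1 the adjusted p of the clock list was 0.00177, and without aks1aks2-1 replicate 3 it was 0.0403, while with an estimated correlation and all arrays the adjusted p was 0.730. CDF5 (AT1G69570) and CDF2 (AT5G39660), Dof factors that repress flowering, differed by -0.44 and -0.35, and COL1 (AT5G15850) by -0.39. Flavonoid genes had a median of 0.00 over 12 members (-0.07 with quantile normalization) and a mean of 0.04 while camera gave the downward direction (adjusted p = 0.664). CHI (AT3G55120) was at -0.17 and UGT75C1 (AT4G14090), well above background on 1 of 3 wild-type arrays, at 0.68. In limma without a block, 0 members of these 4 lists passed over all genes or adjusted over the list alone, and with replicate number as a random block, added after the data were seen, 1 passed over all genes, PYL6 (adjusted p = 0.0486).

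Markers of guard cells and of other cell types were compared to describe the preparations. Guard cell identity and light signalling genes had a median difference of -0.01 over 23 members, or 0.01 with median scaling (adjusted p = 0.661 in camera), with EPF1 (AT2G20875) at 0.42, EPF2 (AT1G34245) at -0.36 and SCAP1 (AT5G65590) at 0.20. Mesophyll markers had a median of -0.01 over 23 members, or 0.01 with median scaling (0.16, -0.16 and -0.02 in replicates 1, 2 and 3; adjusted p = 0.661), with RBCS1A (AT1G67090) at 0.10 and LHCB1.1 (AT1G29920) at -0.15. Leaving out wild type replicate 1 or aks1aks2-1 replicate 2 gave the mesophyll list a downward call, with adjusted p of 4.49e-06 and 8.40e-05, and leaving out aks1aks2-1 replicate 1 or wild type replicate 2 gave an upward call, with 0.0471 and 0.000389. These calls are at the preset correlation, and the correlation estimated for the mesophyll list was 0.785, with an adjusted p of 0.891 over all arrays. Epidermal and cuticle markers had a median of -0.11 over 13 members (adjusted p = 0.106, 0.0198 without aks1aks2-1 replicate 1, and an adjusted p of 0.371 with an estimated correlation). FDH (AT2G26250) and LTP1 (AT2G38540) were at -0.32 and -0.35. CER1 (AT1G02205) had no common direction, with 0.68, -0.01 and -1.75, and neither had PDF1 (AT2G42840), with 0.81, -0.03 and -1.83. The trichome list had 2 measured members, GL2 (AT1G79840) at 0.18 and TRY (AT5G53200) at 0.05, and was not tested. Reference genes had a median of 0.01 over 12 members while camera gave the downward direction (adjusted p = 0.838), with ACT2 (AT3G18780) at -0.19 and GAPC1 (AT3G04120) at 0.13. In limma, 0 members of these 5 lists passed over all genes or adjusted over the list alone.

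**Figure D3:**
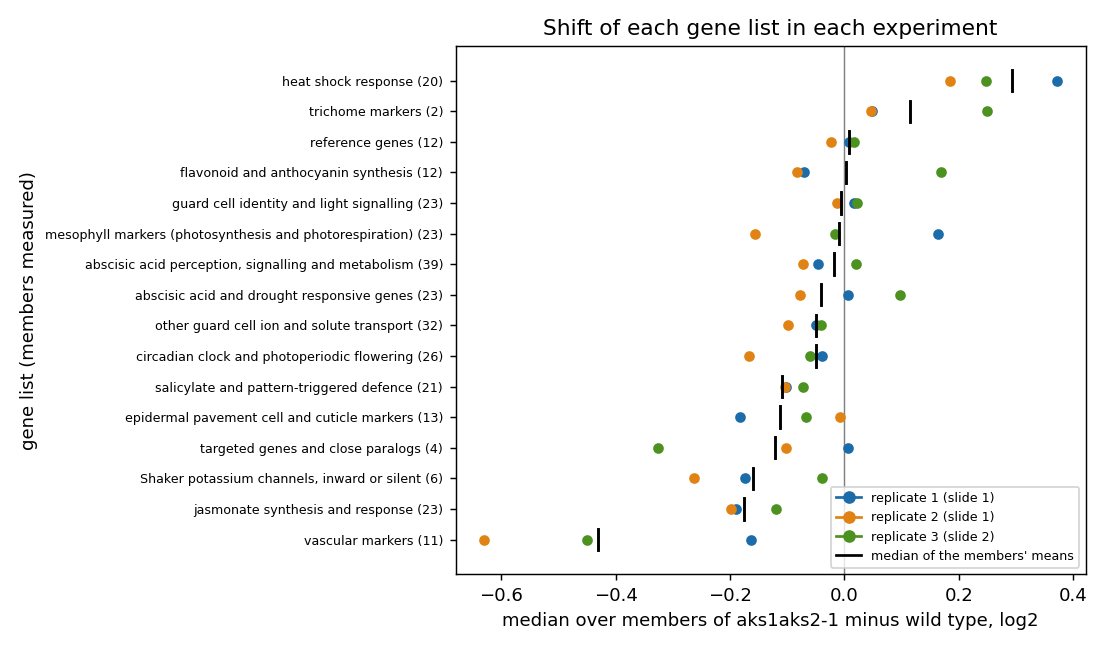
Median over the measured members of each gene list of the log2 difference between aks1aks2-1 and wild type, with 1 point for each replicate number, a bar for the median of the members' mean differences, and the number of measured members in brackets. Heat shock genes lie at 0.29 and vascular markers at -0.43, at opposite ends.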

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

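The 15 added gene-level fits with the replicate number, the list tests on slide 1 alone, the blocked list test with an estimated correlation and the random block for single genes were chosen only after the result was seen. With limma, 0 genes passed under each of the 19 alternatives set in advance, with 61 to 2480 at an unadjusted p under 0.05, the highest with replicate number as a block. The added fits with replicate number as a block gave 0 genes with normexp, with the authors' value table, with robust variance and with quantile normalization, 1 with the strict filter, 259 with trend, 295 with trend and robust, 161 with quantile, trend and robust, 984 with normexp, trend and robust, 320 with the strict filter, trend and robust, 161 with the authors' table, trend and robust, 163 with normexp and quantile, and 227 with normexp, quantile, trend and robust. As a random block the replicate number gave 149, and 268 with trend and robust. The cause of this range was not tested, and 108 genes were shared by the calls of the random block and of the block with trend and robust. The unblocked fit recovered 0 of the simulated changes, so its count of 0 says little about stability.

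Of the lists, 5 passed in the main setting, 6 with replicate number as a block, 3 with normexp and 2 to 6 without 1 array. With an estimated correlation 0 passed, without or with the block. Few residual degrees of freedom are left in these settings, fewer with the block, so their counts of 0 decide little. In the directional test of fry 0 passed, and in its mixed test with the block 5 passed. With an estimated correlation the adjusted p was 0.219 for transport, 0.371 for jasmonate and heat shock, 0.239 for salicylate and 0.104 for vascular genes, and 0.386 with the block added for the first 4 and 0.397 for vascular genes. In fry it was 0.981 for those 4 and 0.910 for vascular genes. With normexp transport and salicylate genes were at 0.0969, and salicylate genes at 0.059 with quantile normalization and 0.0517 without a filter. Abscisic acid signalling passed with slide as a block (0.0429) and with the mean of probes (0.0372), and clock genes with replicate number as a block (0.00742), and the block ended or added no other list call. Leaving out 1 array, which unbalances the experiments, gave adjusted p of 0.0248 to 0.867 for the targeted genes, 0.00724 to 0.504 for transport, 0.0403 to 0.920 for abscisic acid signalling, 0.0403 to 0.953 for abscisic acid responsive genes, 2.62e-05 to 0.867 for jasmonate, 0.0955 to 0.513 for salicylate, 8.11e-09 to 0.622 for heat shock, 0.00177 to 0.867 for clock, 4.49e-06 to 0.939 for mesophyll (upward at 0.0471 and 0.000389), 0.0198 to 0.615 for epidermal and 0.000452 to 0.0866 for vascular genes.

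Of 1146 single-gene values under alternatives, 62 had another sign and 0 of these passed. Among targeted and channel genes, AKT5 at -0.087 with normexp moved by more than the pooled SD within genotypes, a measure of spread chosen after the SD of the pair differences had marked more values. In replicates 1 and 2, 29859 to 32711 probes were flagged well above background, against 41305 and 41888 in replicate 3. The flag came from another software version and another scanner on slide 2, so these counts cannot be compared as detection. The medians of the 5 called lists kept their sign under median scaling, quantile normalization, normexp and the authors' table.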

Other observations

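The tests of the phloem genes, the neighbouring genes, the iron genes and the counts of genes over other splits were chosen only after the result was seen, as was the grouping of genes by symbol. Amino acid transporters were among the families with lower signal in aks1aks2-1 at the preset correlation of camera. That call was lost with an estimated correlation, with an adjusted p of 1.00 for the AAP and UMAMIT families, and 0 of 381 families formed from gene symbols passed in that way. The amino acid permease family AAP had a median of -0.43 over 7 members (-0.09, -0.45 and -0.64 in replicates 1, 2 and 3; adjusted p = 7.09e-05 at the preset correlation), with AAP1 at -0.91, AAP4 at -0.74 and AAP8 at 0.72. The amino acid exporters of the UMAMIT family had a median of -0.22 over 20 members (-0.0044, -0.33 and -0.38; adjusted p = 0.0148), with UMAMIT10 at -1.26, UMAMIT17 at -0.93 and UMAMIT27 at 0.45. The phloem genes of the vascular list were lower in the same comparison, with a median of -0.64, and a lower share of phloem cells stays open for these transporters too. Glycerol-3-phosphate acyltransferase genes had a median of -0.37 over 8 members (-0.58, -0.23 and -0.07; adjusted p = 8.15e-08), with GPAT1 at -0.88 and GPAT3 at -0.0030. The BT genes were at -0.37 over 5 members (-0.30, -0.19 and -0.25; adjusted p = 0.0148), and MYB genes at -0.09 over 55 (-0.14, -0.10 and -0.04; adjusted p = 0.0305), with MYB87 at -1.14 and MYB43 at 0.75. With an estimated correlation the adjusted p was 1.00 for each of these 3 families as well. At the preset correlation 12 families passed, 12 with replicate number as a block, and these 5 in both, all lower and with medians that kept their sign under each scaling. With the block and an estimated correlation, which leave fewer degrees of freedom still, the adjusted p was 0.994 for each of the 5.

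The lower signal of vascular markers lay mostly in the phloem genes, although the xylem genes were lower as well in replicate 2. The 6 phloem genes had a median difference of -0.64 (-0.51, -0.81 and -0.74 in replicates 1, 2 and 3), and the 5 xylem genes one of -0.02 (0.40, -0.56 and 0.04). A lower share of vein cells of every kind in the mutant preparations would lower both only if the xylem signal tracks vein cells. Whether it does in protoplasts was not tested. The phloem median lay below the xylem median by -0.65 ± 0.20 (SE over 3 experiments), with -0.91, -0.25 and -0.78. With only 3 experiments this argues weakly against an equal fall of both sets. Without that assumption it does not decide on the share of vein cells. A slide effect and signal near background are also argued against, since the phloem medians were -0.61 on slide 1 and -0.74 on slide 2 and the 5 phloem genes well above background on all 6 arrays had a median of -0.60. A lower share of vein cells or of phloem cells alone, and lower expression of these genes in aks1aks2-1, may each account for the values. All stay open, as no cell count is given and the last 2 were not tested.

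Iron deficiency genes were noticed among the genes with higher signal, since bHLH38, AT2G30766 (IMA3) and AT2G14247 were in the list of 12, and a stronger iron deficiency response in aks1aks2-1 is a hypothesis that was tested on 13 other iron genes, put together after values of these genes had been seen and signed by their known direction. Of these 13 genes 12 had a signed difference above 0, with a mean of 0.39 and an exact two-sided p of 0.000488 over sign flips of the genes, which carries no weight, since the genes are regulated together and their values had been seen. IMA2 differed by 1.5, with 2.61, 1.84 and 0.03 in replicates 1, 2 and 3. For bHLH39 the difference was 0.92, with -0.22, 1.55 and 1.42. Both were well above background on 5 of 6 arrays. The iron store gene FER1 differed by -0.58, with -0.94, -0.51 and -0.28. The mean signed difference of the 13 genes was 0.65 and 0.55 in replicates 1 and 2 and -0.03 ± 0.15 (SE over genes) in replicate 3. The rise in all 3 experiments that the hypothesis needed was therefore not met. The bound first written counted any experiment at or under 0 against the hypothesis, and by that bound the result went against it. After the values were seen the bound was relaxed, because replicate 3 lay under 0 by less than its SE. Only under that later reading is the hypothesis neither supported nor excluded.

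The largest difference lay beside another large one. AT5G24250, singled out after its values were seen, is next to AT5G24240 on chromosome 5, and its probes at 8233971 to 8234030 and 8233946 to 8234005 (build ath1:Jan2004) differed by -3.39 and -3.12, with -5.45, -4.31 and -0.43 for the first, and were well above background on 1 of 3 aks1aks2-1 arrays. The flanking genes AT5G24230 and AT5G24260 differed by 0.03 and -0.05. A DNA difference at a few places between the lines could place such genes side by side. AT5G24250 is not among the 85 genes with repeated differences, which held 4 pairs within 5 tested genes. Random genes held a median of 2 and a 95th percentile of 4 (share 0.0979 of 10000 draws with as many). Genes that differed between experiments held 5, 19 and 10. The bound first written, no more pairs than the 95th percentile, was met, so by it the count went against the explanation. A later reading, relaxed after the values were seen, left it open. By either reading the count decides little, since differences at a few places would add few pairs among 85 genes. The pair of AT5G24240 and AT5G24250 is not among the pairs counted.

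The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. By limma calls, 10 of the 10 splits gave as many as the real one, each with 0, and the highest other count was 0. With 0 in the real split any count is as many, so this comparison decides nothing. With replicate number as a random block 1 split, the real one, gave as many, with 149 genes against a highest other of 3, and 0 among the other splits that part all 3 pairs. For the lists 1 split gave as many, with 5 against a highest other of 3. Unadjusted p under 0.05 was reached by 82 genes in the real split and by up to 6046 in a split that keeps arrays of one experiment together, which points to the experiments as the main structure of the samples. Of the probes without a locus, 2236 passed the filter on background, and in limma 0 of these passed, with 5 at an unadjusted p under 0.05 and 1 passing with replicate number as a block.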
